A study of Homo sapiens with 16 samples.

How the data were processed

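The series holds 16 single-cell RNA libraries, 1 of blood and 1 of tumour from each of 8 patients with melanoma. Per the labels' protocols, CD8 T cells were sorted by flow cytometry and libraries were made with the version 2 reagent kit of the 10x Chromium single-cell 3' assay, in which each molecule carries a UMI and the 3' end of the transcript is read. Per the submitters' processing notes the data went through Cell Ranger, for which versions 1.3 and 3.0 are named without their roles, on genome build GRCh38, and the matrix headers name version 3.0.2. The deposited matrices hold raw UMI counts, whole numbers per gene and barcode with no normalization, 1 matrix per library. Each deposited barcode had at least 500 UMIs, and the settings of cell calling are not given in the sources used here. Of 33538 genes, 33456 (99.8%) matched by gene ID to GENCODE release 29, from which the GRCh38 coordinates in the text were taken as gene spans, 1-based. No 2 libraries of a group agreed within sampling noise (56 pairs, lowest chi-square per gene 35.5), and a check for mixed-up samples found that 0 of 8 patients disagreed between their libraries. This does not exclude every mix-up, since some libraries best matched another patient's library in the pairing check below.

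Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept. The T-cell gate asked for at least 2 UMIs in all from 8 T-cell receptor complex and CD8 genes and fewer than 3 UMIs in all from 31 genes of other cell types, which left out 2843 filtered cells as other types and 2310 as low in T-cell transcripts, some of them as both. In blood library 1 the gate removed 28.3% of the filtered cells as other types, in blood library 2 7.49%. Per library the gate held 11616399 to 56008290 UMIs. No doublet caller was applied, because scrublet, as implemented in scanpy, set automatic thresholds that marked under 0.1% of cells in 11 libraries, 97.4% in blood library 4 and 6.34% to 14.3% in 4 tumour libraries; leaving out the cells of highest score in each library, at 0.8% per 1000 cells, was added as an alternative after seeing the data. Y-linked genes and the genes of X inactivation, 110 in all, were left out of every fit. The CCL5 gate took T-gate cells thinned at random to 1000 UMIs with at least 1 UMI of CCL5 and none of CCR7, and the ENTPD1 arms took tumour cells thinned likewise with at least 1 or no UMI of ENTPD1, where both arms held at least 50 cells. CCL5 and CCR7 were left out of the test in the CCL5 gate and ENTPD1 of that between its arms, while the genes of the T-cell gate were tested like all others. Genes with near-identical copies, such as HSPA1A and HSPA1B, CCL3, CCL4 and CCL4L2, the KIR, KLRC, XCL and HLA families and HBA1, can lose or trade UMIs between copies, so their single levels are uncertain.

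Counts were summed per library and tested in edgeR 4.0.16 with TMM normalization, filterByExpr, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors of log2 fold changes were computed as the absolute log2 fold change over the square root of the F statistic. The comparisons of tumour with blood had no block, and that of ENTPD1 arms had the library as block. The libraries are paired by patient, as their titles give the patient number. In a check of the pairing, the correlation over 4015 genes between the deviations of a patient's blood and tumour libraries from their group means lay between −0.06 and 0.59, the best match was the own partner for 5 of 8 blood and 6 of 8 tumour libraries, and the highest correlation with another patient's library was 0.40. The fit with patient as a replicate block was therefore run as the alternative, and called 1753 genes higher and 1463 lower in the T-cell gate and 1926 and 1741 in the CCL5 gate. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the 15 functional lists and, apart from them, over the lists of other cell types with at least 2 measured members. DESeq2 1.42.0 was the other count test. The settings were tested on simulated counts at the real library sizes with 200 changed genes. For tumour against blood, each gene had 1 mean over all libraries, with no patient effect. The pairing of the real libraries was therefore not imitated there, and these rates do not cover it. A change of 1 log2 was called for 48% of genes in the first comparison, 50% in the CCL5 gate and 92% between ENTPD1 arms, a change of 0.5 log2 for 5%, 5% and 49%, with 3, 5 and 8 false calls among 12794, 10500 and 8907 unchanged genes.

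The lists were fixed before the data were examined, as were the tests, the gates and most of the other settings tried. The functional lists were naive and central memory, circulating cytotoxic effector, inhibitory receptors and exhaustion, tissue residency, costimulation and activation, cytokines and chemokines, chemokine receptors, cell cycle, interferon response, heat shock, immediate early, glycolysis and hypoxia, oxidative phosphorylation, MAIT and killer receptors, and those of other cell types were melanocyte, myeloid, B and plasma, CD4 and regulatory, gamma delta T, erythroid, platelet, stroma and endothelium, and keratinocyte. The genes of other cell types used in the gate come from the latter lists, so that their levels after it are capped. Named genes followed a rule fixed with the lists. They are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold, changed in the same direction in every patient and with a mean of at least 20 CPM, leaving out receptor and immunoglobulin segments, mitochondrial, ribosomal and clone-named genes. To these were added, per functional list, the 3 members with the largest change past the threshold and the 1 of highest mean CPM that did not pass, and per list of another cell type the member of highest mean CPM. The genes S100A8, S100A9, LYZ, CST3, MZB1 and IGKC, the granzyme genes and the transcription factors of the closing section fall outside this rule and were chosen after their values were seen.

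Shares of cells with a UMI were computed per library from cells thinned to 1000 UMIs, and group means were compared by a two-sided exact permutation test with Benjamini-Hochberg adjustment over 25 shares. Intervals are exact Clopper-Pearson intervals at 95% and cover counting error only. List levels were the mean over genes of log2 CPM with a prior count of 2. Cells were clustered in scanpy 1.11.5 on counts scaled to 10000 and log-transformed, with 2000 variable genes chosen with the patient as batch and without receptor, immunoglobulin, mitochondrial, ribosomal and sex-linked genes, 30 principal components, 15 neighbours and Leiden resolution 1, and named by markers fixed beforehand. Alternatives were another normalization (the RLE size factors of DESeq2 in edgeR), DESeq2, no filter on low counts, each patient left out in turn, stricter or no quality filters, other T-cell definitions, other thinning, a stricter CCL5 gate and fewer genes in the library size. After seeing the data, runs without the cells of highest doublet score, without barcodes that blood library 4 and tumour library 5 share, and without patients 1 and 2 were added. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3.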

Results

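Single-cell 3' gene expression was measured in CD8 T cells, the cytotoxic lymphocytes that recognise and kill tumour cells, sorted by flow cytometry from the blood and the tumour of 8 patients with melanoma. Each patient gave 1 blood and 1 tumour library, so that 8 blood libraries were set against 8 tumour libraries. The files held 173061 barcodes, 87361 from blood and 85700 from tumour, with 3924 to 20949 barcodes and 18100324 to 59867301 unique molecular identifiers (UMIs) per library. After filters on detected genes and mitochondrial share 165097 cells remained, and 160707 of them, 82686 from blood and 78021 from tumour, passed a gate on T-cell transcripts. Per library the gate kept 3072 to 20546 cells with a median of 1981 to 3712 UMIs and 737 to 1208 genes per cell. The gate kept 70.3% of the filtered cells of blood library 1, 91.0% of blood library 2, 92.0% of tumour library 1 and 94.9% to 99.5% of those of the other 13 libraries. Counts were summed over the cells of each library, so the replicate in each comparison below was the patient's library and not the cell.

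CD8 T cells from tumour differed from those in blood by a gain of inhibitory receptors, tissue-residency genes, costimulatory receptors and secreted cytokines. Heat shock genes were higher and genes of circulating cytotoxic effector cells lower as well, but these 2 lists lost their calls with an estimated correlation between genes (adjusted p = 0.147 each). With the patient as a replicate block on top of that, only the cytokine list kept its call (adjusted p = 0.0436). ZBED2 rose by a log2 fold change of 9.84 ± 0.63, from 0.0316 to 30.6 CPM, below a mean of 20 CPM over the libraries of both tissues. The transcript with the largest gain among those of at least that mean was CXCL13 (ENSG00000156234, chromosome 4, 77511753 to 77611834), a chemokine that attracts B cells. CXCL13 rose from 1.16 ± 1.17 CPM in blood to 545 ± 500.5 CPM in tumour (mean ± SD, n = 8 libraries each). Its log2 fold change was 8.85 ± 0.79 (SE, adjusted p = 1.46e-06, edgeR quasi-likelihood test), and it was higher in tumour in 8 of 8 patients. HAVCR2 (ENSG00000135077, chromosome 5, 157085832 to 157142869), which encodes the inhibitory receptor TIM-3, rose from 9.31 ± 7.16 to 194 ± 110.2 CPM (4.39 ± 0.53, adjusted p = 2.95e-05, 8 of 8 patients). FGFBP2 (ENSG00000137441, chromosome 4, 15960243 to 15969309), a marker of circulating cytotoxic lymphocytes, fell from 344 ± 233 to 32.9 ± 54.9 CPM (−3.40 ± 0.72, adjusted p = 0.00301, lower in 8 of 8 patients). Tumour library 1 weighed on that mean, at 168 CPM against 4.15 to 24.2 CPM in the other tumour libraries. Of 13077 genes tested, 1519 were higher and 1056 lower in tumour at a false discovery rate of 0.05, 807 and 352 of them by at least 1 on the log2 scale. The count of lower genes was 699 without patient 4 and 649 without patient 7. The counts of changes of at least 1 log2 were 1285 higher and 586 lower with DESeq2, and 1248 were higher without the filter on low counts.

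Inhibitory receptors and genes of exhaustion, the state of T cells under lasting antigen contact, rose as a group: 19 of 22 list members were higher and none lower (adjusted p = 1.41e-24). Besides CXCL13 and HAVCR2, the list's risen members included VCAM1, an adhesion ligand (5.18 ± 0.62), LAYN, a hyaluronan receptor (5.80 ± 0.63), and MYO7A, an unconventional myosin, at 8.66 ± 6.06 CPM in tumour against 0.0459 ± 0.0427 CPM in blood. PRDM1, which encodes the transcription factor BLIMP-1, did not pass (0.26 ± 0.47, adjusted p = 0.736). Of 11 tissue-residency genes 8 were higher and none lower, 9 adjusted over the list alone (adjusted p = 6.61e-09). They included ITGA1, the collagen-binding integrin CD49a (3.63 ± 0.39), CXCR6, a chemokine receptor of resident cells (3.24 ± 0.51), and the potassium channel gene KCNK5 (3.40 ± 0.40). RUNX3, a transcription factor of resident cells, was at 0.58 ± 0.24 (adjusted p = 0.0939). Of 14 costimulation and activation genes 11 were higher (adjusted p = 1.05e-10). Among them were the TNF receptor family members TNFRSF18, or GITR (4.38 ± 0.58), and TNFRSF9, or 4-1BB (4.25 ± 0.45), and the CD28 family member ICOS (2.52 ± 0.31). CD74, the invariant chain of MHC class II, did not pass (0.58 ± 0.30, adjusted p = 0.188). Of 15 cytokine and chemokine genes 11 were higher (adjusted p = 8.16e-11), led by the chemokines CCL3 (3.93 ± 0.48) and CCL4L2 (3.80 ± 0.57) and the macrophage growth factor CSF1 (3.65 ± 0.26). CCL5, a chemokine abundant in both tissues at 4256 ± 1838 CPM in blood and 4368 ± 856 CPM in tumour, did not pass (0.04 ± 0.25, adjusted p = 0.935). These 4 lists kept their calls with an estimated correlation between genes (adjusted p = 0.0102, 0.00953, 0.0102 and 0.00953 in the order given). No other list did in this comparison. With the patient as a replicate block as well, these values were 0.0555, 0.0671, 0.0671 and 0.0436, so that only the cytokine list then kept its call. Here and below, a list's count adjusted over the list alone equalled that over all genes unless given.

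Genes of the heat shock response, chaperones induced by protein-damaging stress, also rose together in tumour. Of 15 members 14 were higher (adjusted p = 5.28e-10; adjusted p = 0.147 with an estimated correlation). HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910) went from 2.53 ± 1.77 to 426 ± 388 CPM (7.45 ± 1.06), with HSPA1B at 6.17 ± 1.01 and HSPA1A at 6.07 ± 0.82. HSPA5, a chaperone of the endoplasmic reticulum, was at 0.28 ± 0.19 (adjusted p = 0.311). The tumour libraries were uneven in this. HSPA6 stood at 4.17, 9.60 and 18.9 CPM in those of patients 4, 2 and 5 and between 389 and 905 CPM in the other 5. Of 16 interferon-response genes 12 were higher, 15 adjusted over the list alone (adjusted p = 3.33e-09; adjusted p = 0.146 with an estimated correlation). OASL (2.64 ± 0.35), IFIT1 (2.48 ± 0.43) and IFIT3 (1.96 ± 0.38) led it. Of 16 genes of glycolysis and hypoxia 8 were higher, 9 higher and 1 lower adjusted over the list alone (adjusted p = 4.38e-04; adjusted p = 0.147 with an estimated correlation). They included HIF1A, the oxygen-sensing transcription factor (1.28 ± 0.15), and hexokinase 2, HK2 (1.76 ± 0.45; adjusted p = 0.185 with every filtered cell kept). Enolase 1, ENO1, was at 0.16 ± 0.17 (adjusted p = 0.565). Of 18 immediate early genes, transcribed within minutes of a stimulus, 6 were higher, and 1 was lower adjusted over the list alone (adjusted p = 0.0177; adjusted p = 0.592 with an estimated correlation). NR4A1 (3.29 ± 0.71), ATF3 (2.92 ± 0.76) and JUND (1.78 ± 0.34) led the list, and JUNB was at −0.33 ± 0.39 (adjusted p = 0.586). For ATF3, blood library 8 stood at 49.8 CPM against 1.13 to 5.26 CPM in the other blood libraries. None of the 21 cell cycle genes passed on its own, although the list lay higher in tumour than other genes (adjusted p = 0.0203; adjusted p = 0.632 with an estimated correlation).

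Genes of circulating cytotoxic effector cells were lower in tumour: 11 of 18 fell and none rose, 13 adjusted over the list alone (adjusted p = 2.37e-08; adjusted p = 0.147 with an estimated correlation). CX3CR1, the fractalkine receptor of patrolling effector cells, fell from 11.9 ± 8.01 to 0.855 ± 1.29 CPM (−4.02 ± 0.66), and S1PR5, a sphingosine 1-phosphate receptor, from 71.4 ± 42.2 to 5.66 ± 5.74 CPM (−3.71 ± 0.59). NKG7, a granule protein gene of the same list, was at −0.55 ± 0.33 (adjusted p = 0.257). Among killer receptors, 5 of 13 were higher and 2 lower (adjusted p = 0.243). KIR2DL4 was at 6.15 ± 0.81 on the higher side, with KLRF1 (−3.95 ± 0.78) and the adaptor TYROBP (−3.12 ± 0.73) on the lower. Of 7 genes of mucosal-associated invariant T (MAIT) cells, only KLRB1, or CD161, fell (−2.17 ± 0.52), and the list did not pass (adjusted p = 0.136). None of the 14 genes of naive and central memory cells passed (adjusted p = 0.243), LTB being at −0.49 ± 0.32 (adjusted p = 0.295). Of 8 chemokine receptor genes 2 were higher, among them CXCR3 (1.43 ± 0.22), and CCR10 (−2.06 ± 0.43) was lower. The counts were 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0737). CXCR4 was at 0.75 ± 0.31 (adjusted p = 0.0991, and 0.0385 without patient 2). Of 16 genes of oxidative phosphorylation NDUFS5 was higher (0.44 ± 0.11) and NDUFB9 lower (−0.77 ± 0.12), and the list did not pass (adjusted p = 0.226). Outside the lists, among genes with a mean of at least 20 CPM, the largest changes shared by every patient included rises of 2 genes. These were the phosphatase gene DUSP4 (4.27 ± 0.47) and haem oxygenase 1, HMOX1 (4.19 ± 0.74). The largest changes also included a fall of SH3BP5 (−1.63 ± 0.31), PXN (−1.63 ± 0.28), P2RY8 (−1.58 ± 0.21), RASGRP2 (−1.52 ± 0.23) and AES (−1.42 ± 0.12).

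Some genes of the lists of other cell types differed between the tissues too. Whether their transcripts came from such cells or from the T cells themselves was not tested. KRT10 of the keratinocyte list, for one, was at 232 ± 36.7 CPM in blood and 159 ± 44.1 CPM in tumour. The monocyte genes S100A8 (−6.31 ± 1.39), S100A9 (−5.06 ± 1.25) and LYZ (−3.53 ± 1.04) were lower in tumour, 3 of 7 measured myeloid genes (adjusted p = 0.223 for the list). The gate had removed 1237 barcodes with other cells' transcripts from blood library 1 and 403 from blood library 2. Without patients 1 and 2, 1343 genes were higher and 962 lower. Then 2 more lists passed, killer receptors upward (adjusted p = 0.0116) and MAIT genes downward (adjusted p = 0.0425). Of 6 genes of B and plasma cells 4 were higher in tumour, 5 adjusted over the list alone (adjusted p = 0.0153; adjusted p = 0.246 with an estimated correlation). They included MZB1 (2.90 ± 0.44), IGKC (5.58 ± 1.19) and CD79B (0.72 ± 0.24, adjusted p = 0.0435). The call of CD79B was lost with the patient as a replicate block (0.64, adjusted p = 0.0838), without the filter on low counts, with every filtered cell kept, and without any 1 of patients 2, 3, 4, 5, 7 and 8, where adjusted p lay between 0.0695 and 0.132. Of the melanocyte list only S100B was measured (0.12 ± 0.86, adjusted p = 0.940), and of the erythroid list only HBA1, which was lower (−1.86 ± 0.56), though not without patient 4, 5 or 7 (adjusted p = 0.0574, 0.0835 and 0.0673), with every filtered cell kept (0.155) or with clusters in place of the gate (0.280). No platelet gene was measured. None of 3 genes of CD4 and regulatory T cells, 4 of gamma delta T cells and 2 of stroma and endothelium passed (adjusted p = 0.759, 0.759 and 0.759). Of 2 keratinocyte genes KRT10 was lower (−0.54 ± 0.16; adjusted p = 0.381 for the list), a call lost without any 1 of patients 4, 5, 6 and 7 (adjusted p = 0.0614 to 0.0781).

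**Figure D1:**
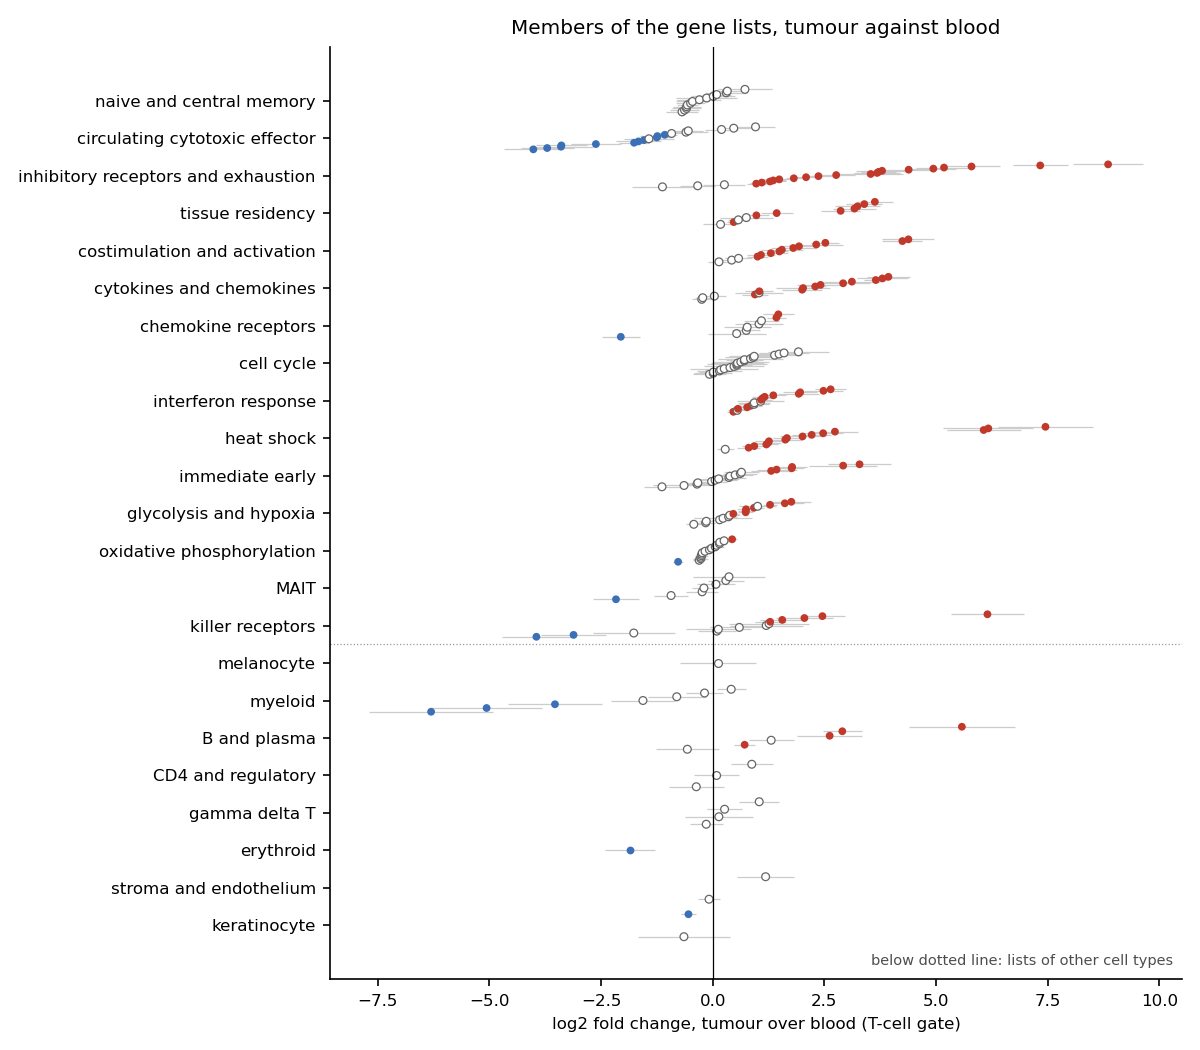
Log2 fold change of each measured list member, tumour over blood, in the T-cell gate, with bars of 1 SE; filled points passed a false discovery rate of 0.05 and open points did not, and lists of other cell types stand under the dotted line. Of 22 members of the exhaustion list 19 lie to the right of 0 as filled points, and 11 of 18 members of the circulating effector list lie to the left.

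Counting cells showed how widely these transcripts were spread. With every cell thinned to 1000 UMIs, CXCL13 was found in 19.2% ± 12.0 of tumour cells and 0.0487% ± 0.0484 of blood cells (mean ± SD over 8 libraries each; adjusted p = 7.77e-04, two-sided exact permutation test over 25 shares, higher in 8 of 8 patients). The inhibitory receptor LAG3 was found in 30.1% ± 14.5 against 7.54% ± 2.41, and TIGIT, another, in 22.0% ± 9.75 against 8.47% ± 3.69. HAVCR2 was in 16.2% ± 8.02 against 0.826% ± 0.756, CTLA4 in 13.0% ± 8.28 against 1.05% ± 0.824, and PDCD1, or PD-1, in 8.69% ± 3.26 against 3.63% ± 2.37. The ectonucleotidase gene ENTPD1, or CD39, was found in 9.48% ± 6.62 against 0.797% ± 0.955, and TNFRSF9 in 12.1% ± 7.10 against 0.742% ± 0.464. CXCR6 was in 11.7% ± 6.32 against 1.29% ± 0.944, and IFNG, the interferon gamma gene, in 23.8% ± 9.53 against 6.02% ± 6.22. For IFNG, blood library 8 stood at 20.6%, above the 19.2% of tumour library 8, and the other blood libraries at a mean of 3.93%. TOX, a transcription factor of exhausted cells, was in 5.88% ± 2.25 against 2.72% ± 1.16, and LAYN in 2.12% ± 1.39 against 0.0407% ± 0.0626. HSPA1A was found in 27.5% ± 21.2 against 1.27% ± 0.546, and ITGAE, the integrin CD103, in 7.62% ± 1.40 against 5.20% ± 1.03. With MKI67 these made 15 shares higher in tumour, with adjusted p from 7.77e-04 to 0.0183. The smallest raw p these permutations can give is 0.000155. FGFBP2 fell from 22.4% ± 13.7 of blood cells to 2.22% ± 3.26 of tumour cells and CX3CR1 from 1.07% ± 0.743 to 0.0593% ± 0.0913 (adjusted p = 7.77e-04 for each, exact permutation test, lower in 8 of 8 patients). The tumour means without tumour library 1 were 1.08% and 0.0278%.

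The other 8 shares did not pass the exact permutation test. The naive-cell receptor CCR7 was found in 4.34% ± 5.60 of blood and 7.45% ± 3.98 of tumour cells (adjusted p = 0.258, and 0.00937 without patient 6). The transcription factor TCF7 was in 9.50% ± 4.84 and 7.15% ± 1.95 (adjusted p = 0.264), and the interleukin 7 receptor gene IL7R in 21.5% ± 5.54 and 23.6% ± 11.0 (adjusted p = 0.644). Granzyme genes were in many cells of both tissues. GZMK was in 40.2% ± 20.1 of blood and 54.1% ± 9.48 of tumour cells (adjusted p = 0.137, and 0.0478 without patient 3) and GZMB in 23.3% ± 13.7 and 32.3% ± 13.8 (adjusted p = 0.258). ZNF683, or HOBIT, was in 2.27% ± 1.53 and 4.04% ± 3.76 (adjusted p = 0.277) and CD4 in 0.0655% ± 0.119 and 0.00357% ± 0.00660 (adjusted p = 0.411). TCF7 was in 8.23% ± 5.84 and 5.03% ± 2.02 of the cells with PDCD1 (adjusted p = 0.208). MKI67, a mark of dividing cells, went from 0.534% ± 0.547 to 1.67% ± 1.44. Its call was lost in the sign-flip test within patients, the replicate block for shares (adjusted p = 0.0574), without thinning (0.155), without patient 4 (0.0617) and without patient 5 (0.0591), each from exact permutations.

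Thinning left out 936 blood and 3398 tumour cells with under 1000 UMIs, and without it the shares were higher in both tissues. CXCL13 was then in 29.1% of tumour and 0.218% of blood cells, HAVCR2 in 32.2% and 2.59%, and LAG3 in 51.6% and 19.8%. PDCD1 was in 21.9% and 10.1%, ENTPD1 in 22.3% and 2.54%, and FGFBP2 in 4.72% and 37.0%. For reference, the same genes were read in barcodes with at least 3 UMIs of other cell types' genes and under 2 of the gate's T-cell genes. Such barcodes, 612 in blood and 77 in tumour, could still hold some T-cell transcripts and were thinned to 1000 UMIs like the T cells. These hold other cells' own transcripts as well as free RNA and are pooled over libraries, so they do not measure the background of T cells alone. Before thinning they had a median of 3906.5 and 3721 UMIs against 2535 and 2754 in T cells. In those of tumour, CXCL13, HAVCR2 and IFNG were each in 3.90% (exact 95% interval 0.811% to 11.0%). LAG3, TIGIT, CTLA4, CXCR6, FGFBP2 and MKI67 were each in 1 of 77 (0.0329% to 7.02%). PDCD1, ENTPD1, LAYN, TOX, TNFRSF9, CX3CR1 and ZNF683 were in 0 of 77, which an exact 95% interval bounds at 4.68%. The tumour shares of ITGAE, MKI67, LAYN, FGFBP2, CX3CR1 and ZNF683 lay within these intervals, ITGAE being in 9.09% (3.73% to 17.8%) of these barcodes. HSPA1A was in 58.4% of them, pooled over libraries whose T-cell shares ran from 2.31% to 61.9%. In blood, HAVCR2 was in 3.43%, ENTPD1 in 8.17%, ITGAE in 5.88%, CX3CR1 in 1.63%, HSPA1A in 2.61% and CD4 in 6.70% of them, all above the blood T-cell shares, so that for these genes they give no background. The blood T-cell shares of CXCL13, LAYN and MKI67 lay within the 0.601% that an exact 95% interval allows for 0 of 612.

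**Figure D2:**
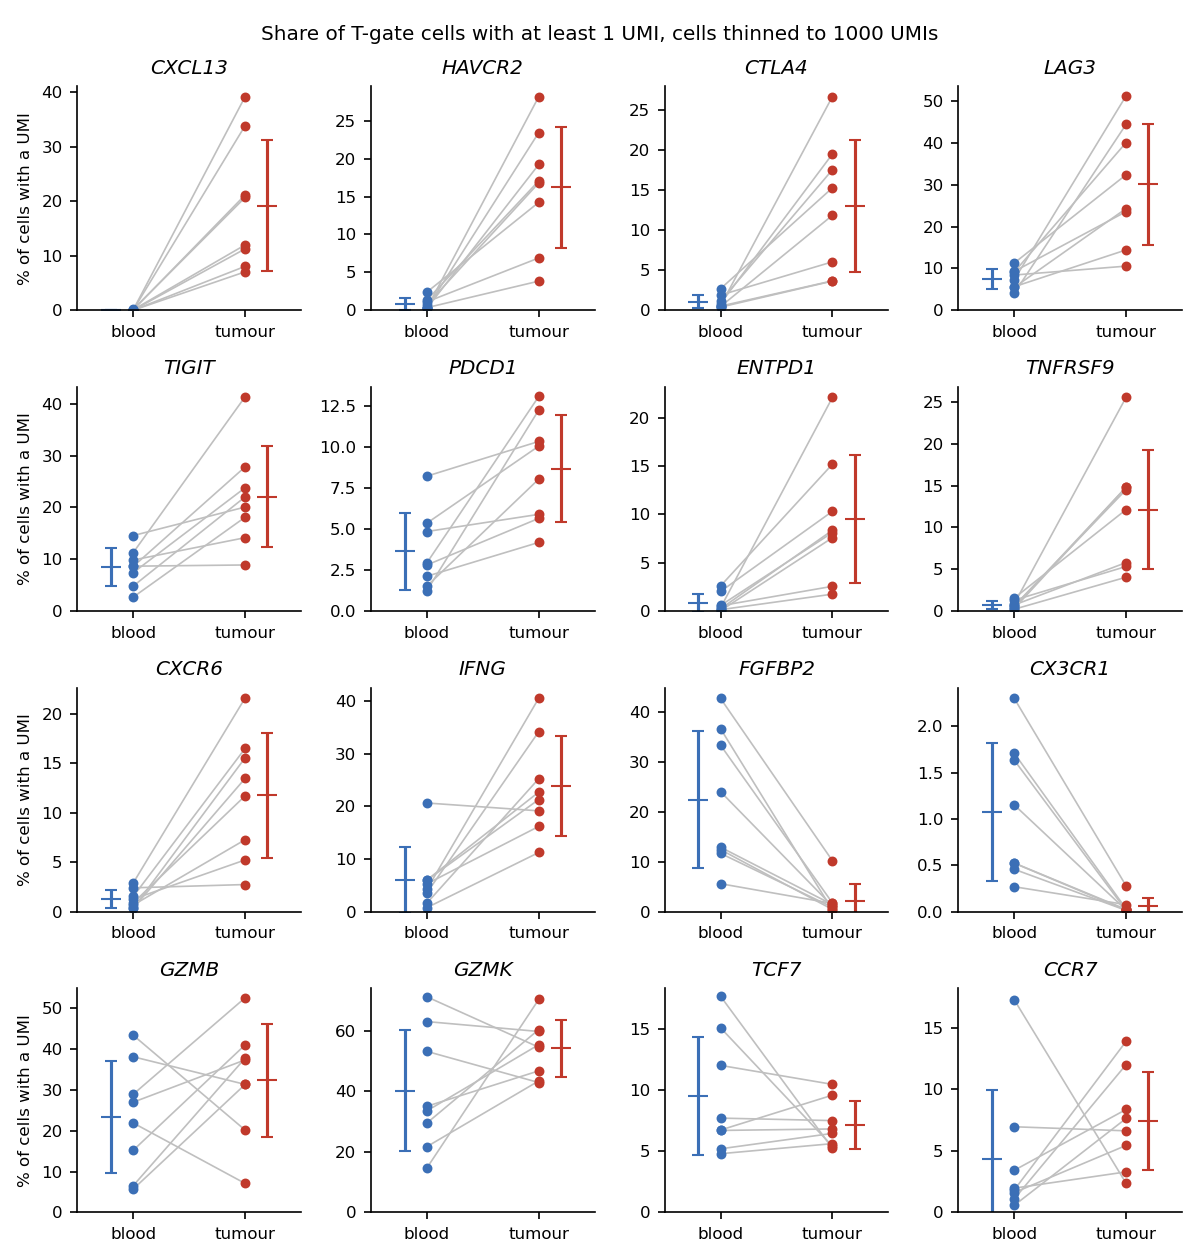
Percent of T-gate cells with at least 1 UMI of 16 genes after thinning to 1000 UMIs per cell, in the 8 blood and 8 tumour libraries; grey lines join libraries of 1 patient, and side marks give mean and SD. CXCL13 rises from a mean of 0.0487% to 19.2% and FGFBP2 drops from 22.4% to 2.22%, while GZMK and TCF7 overlap between tissues.

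Naive cells lack CCL5, so the tissues were next compared over cells with CCL5 and without CCR7. The same kinds of genes separated tumour from blood among these antigen-experienced cells. CXCL13 rose from 1.04 ± 1.23 to 586 ± 509 CPM (9.29 ± 0.68, adjusted p = 8.74e-08) and HAVCR2 from 10.5 ± 9.04 to 245 ± 134 CPM (4.61 ± 0.55). CX3CR1 fell from 13.3 ± 7.89 to 0.645 ± 0.953 CPM (−4.80 ± 0.52, adjusted p = 6.51e-06), and each of these changes was seen in 8 of 8 patients (mean ± SD, n = 8 libraries each). The gate held 66753 blood and 58946 tumour cells, 2488 to 19355 per library. It took in 82.3% ± 21.9 of the thinned blood cells and 79.1% ± 11.1 of the thinned tumour cells (mean ± SD over libraries). On average it therefore left out no larger share of cells in blood than in tumour. Single libraries ranged from 32.8% in blood library 6 to 96.6% in blood, and from 63.2% to 94.4% in tumour. Of 10827 genes 1532 were higher and 1190 lower in tumour, 723 and 314 of them by at least 1 log2. The count of lower genes was 780 without patient 7, and the counts of at least 1 log2 were 1087 and 536 with DESeq2 and 1179 and 532 without the filter on low counts. Without patients 1 and 2, 1289 were higher and 1024 lower. No gene's difference between this gate and the whole T-cell gate was tested.

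The exhaustion list had 18 of 21 members higher, with 1 lower adjusted over the list alone (adjusted p = 7.32e-22), including VCAM1 (5.09 ± 0.50), LAYN (6.58 ± 0.72) and the transcription factor gene ETV1 (5.28 ± 0.52). PRDM1 was at 0.30 ± 0.44 (adjusted p = 0.654). Of 11 tissue-residency genes 8 were higher, 9 adjusted over the list alone (adjusted p = 2.74e-08), with ITGA1 at 4.01 ± 0.42 and CXCR6 at 3.45 ± 0.42. RUNX3 passed only with the replicate block (0.53, adjusted p = 0.0353), with DESeq2 or without patient 3 or 8 (adjusted p = 0.0353 to 0.0476). It was otherwise at 0.60 ± 0.23 (adjusted p = 0.0583). Costimulation and activation genes were higher in 11 of 14 cases, 13 adjusted over the list alone (adjusted p = 1.34e-11), with TNFRSF18 at 4.90 ± 0.56, TNFRSF9 at 4.16 ± 0.41 and ICOS at 3.09 ± 0.30. Cytokine and chemokine genes were higher in 10 of 13 cases (adjusted p = 3.43e-10), with CCL3 at 3.89 ± 0.46 and CSF1 at 3.97 ± 0.29. Chemokine receptor genes were higher in 3 of 4, 4 adjusted over the list alone (adjusted p = 0.00108), with CXCR3 at 1.57 ± 0.23. These 5 lists, and no other here, kept their calls with an estimated correlation (adjusted p = 0.0122, 0.0108, 0.0122, 0.0122 and 0.0122). With the replicate block as well the values were 0.0467, 0.0587, 0.0587, 0.0310 and 0.0467, which left out the residency and costimulation lists. Heat shock genes were higher in 14 of 15 cases (adjusted p = 6.37e-10; adjusted p = 0.126 with an estimated correlation), with HSPA6 at 7.45 ± 1.00. Interferon-response genes were higher in 15 of 16 (adjusted p = 5.78e-09; adjusted p = 0.113 with an estimated correlation), with OASL at 2.73 ± 0.38. Genes of glycolysis and hypoxia were higher in 7 of 14 cases, 9 higher and 1 lower adjusted over the list alone (adjusted p = 5.15e-04; adjusted p = 0.126 with an estimated correlation), with HIF1A at 1.25 ± 0.14 and the lactate dehydrogenase gene LDHA at 1.09 ± 0.21.

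Within this gate 7 of 21 cell cycle genes were higher in tumour (adjusted p = 5.15e-04; adjusted p = 0.461 with an estimated correlation), among them cyclin A2, CCNA2 (2.32 ± 0.52), UBE2C (2.21 ± 0.65) and the mitotic kinase gene CDK1 (2.07 ± 0.55). Immediate early genes were higher in 5 and lower in 1 of 18 cases, 6 higher adjusted over the list alone (adjusted p = 0.0325; adjusted p = 0.575 with an estimated correlation), NR4A1 being at 3.23 ± 0.67. The circulating effector list fell again, 13 of 18 members being lower and none higher, with 1 higher adjusted over the list alone (adjusted p = 7.42e-11; adjusted p = 0.0564 with an estimated correlation). It included ASCL2 (−3.92 ± 0.53), S1PR5 (−3.85 ± 0.47), FGFBP2 (−3.56 ± 0.71) and PRSS23 (−2.96 ± 0.44). Of 13 naive and central memory genes FOXP1 (−0.69 ± 0.16) and S1PR1 (−1.21 ± 0.36; adjusted p = 0.059 without patient 4) fell (adjusted p = 0.0435; adjusted p = 0.461 with an estimated correlation). KLF2, a factor that keeps T cells in circulation, fell only with the replicate block (−1.15, adjusted p = 0.0367) or the stricter CCL5 gate (adjusted p = 0.049), against −0.88 ± 0.39 (adjusted p = 0.102). Of 7 MAIT genes KLRB1 (−2.17 ± 0.46) and NCR3 (−1.04 ± 0.36) fell (adjusted p = 0.0491; adjusted p = 0.389 with an estimated correlation). The list's call was lost with another normalization (adjusted p = 0.0524), and that of NCR3 without patient 1, 3, 4, 7 or 8 (adjusted p = 0.0524 to 0.102), without patients 1 and 2 (0.0534) and among cells with CD8 and no CD4 transcript (0.0606), with NCR3 at −0.93 to −1.11 in all of these. Killer receptors were higher in 4 and lower in 2 of 10 cases (adjusted p = 0.363, and 0.0447 upward without patients 1 and 2). Oxidative phosphorylation genes were higher in 1 and lower in 2 of 16, the latter 1 adjusted over the list alone (adjusted p = 0.213). Outside the lists, among genes with a mean of at least 20 CPM, the transcription factor gene ID3 (4.19 ± 0.49) was among the largest rises. TGFBR3 (−2.15 ± 0.24) and the kinase gene FGR (−3.12 ± 0.46) were among the largest falls there. Of other cell types, 4 of 5 B and plasma genes were higher (adjusted p = 0.0116; adjusted p = 0.143 with an estimated correlation), with MZB1 at 3.12 ± 0.43. Of the others, 1 of 3 myeloid genes was lower (CST3, −1.87 ± 0.67; adjusted p = 0.821 for the list), and KRT10 was lower (−0.58 ± 0.17), though not without patient 4, 5 or 7 (adjusted p = 0.0519 to 0.0605). Neither 3 CD4 and regulatory genes (adjusted p = 0.821, with a median of 0.01 and a mean of −0.05), nor 4 gamma delta genes (adjusted p = 0.821), nor S100B (−0.02 ± 0.81), nor PECAM1 of the endothelial list (−0.17 ± 0.24) passed, and no erythroid or platelet gene was measured.

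ENTPD1, the gene of CD39, marks tumour CD8 T cells that have met antigen repeatedly, so cells with and without its transcript were compared inside each tumour library. Cells with ENTPD1 held more of the transcripts of exhaustion, costimulation and killer receptors and less of those of naive and central memory cells. CXCL13 rose from 523 ± 489 CPM in ENTPD1-negative to 1143 ± 775 CPM in ENTPD1-positive cells (mean ± SD, n = 8 libraries; 1.21 ± 0.13, adjusted p = 1.74e-09, higher in 8 of 8 libraries). The largest rises of at least 20 CPM were those of the hair keratin gene KRT86 (ENSG00000170442, chromosome 12, 52249300 to 52309163; 1.43 ± 0.19) and of TNFSF4, the OX40 ligand (ENSG00000117586, chromosome 1, 173183734 to 173207313; 1.31 ± 0.12). IL7R (ENSG00000168685, chromosome 5, 35852695 to 35879603), whose product keeps memory cells alive, fell from 419 ± 234 to 125 ± 82.9 CPM (−1.58 ± 0.10, adjusted p = 3.71e-16, lower in 8 of 8 libraries). Of 9242 genes 430 were higher and 564 lower in ENTPD1-positive cells, 20 and 81 of them by at least 1 log2. The positive arms held 82 to 2879 cells per library and the negative arms 3139 to 11217, and cells whose ENTPD1 transcript was not captured stand in the negative arm. Without the library as a replicate block, which leaves the differences between patients in the error, edgeR called no gene in either direction and 655 genes had an unadjusted p under 0.05. DESeq2 with the block called 260 and 394. Thinning to 500 UMIs, which drops tumour library 1, left 185 and 294, and 282 were higher without patient 8. The counts of at least 1 log2 were 37 higher with DESeq2, 31 higher and 210 lower without the filter on low counts, 13 higher among cells with CD8 and no CD4 transcript, 42 higher without patient 4 and 10 without patient 5, while 893 genes in all were lower without that filter.

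In the exhaustion list 18 of 21 members were higher and 1 lower in ENTPD1-positive cells, 19 higher adjusted over the list alone (adjusted p = 1.03e-33), with LAYN at 1.14 ± 0.11, VCAM1 at 1.08 ± 0.10 and HAVCR2 at 0.99 ± 0.09. The receptor gene CD244 was at 0.26 ± 0.14 (adjusted p = 0.296). Costimulation and activation genes were higher in 12 of 14 cases, with 1 lower adjusted over the list alone (adjusted p = 8.54e-19), led by TNFRSF18 (1.11 ± 0.11), TNFRSF9 (0.94 ± 0.10) and CD38 (0.68 ± 0.10). Killer receptors were higher in 4 of 5 cases (adjusted p = 5.30e-07), with KIR2DL4 at 1.15 ± 0.13 and KLRD1, or CD94, at 0.43 ± 0.07. Naive and central memory genes were lower in 12 of 14 cases, 13 adjusted over the list alone (adjusted p = 2.12e-35), with CCR7 at −1.75 ± 0.12, LEF1 at −1.68 ± 0.16 and S1PR1, the receptor for leaving tissue, at −2.12 ± 0.37. S1PR1 was at 0 to 5.08 CPM in the ENTPD1-positive arms, so that the size of its fall rests on few molecules. These 4 lists, and no other here, kept their calls with an estimated correlation (adjusted p = 0.0241, 0.0241, 0.0256 and 0.0241). Cell cycle genes were higher in 6 of 21 cases, 12 adjusted over the list alone (adjusted p = 1.24e-07; adjusted p = 0.158 with an estimated correlation), with TOP2A at 0.70 ± 0.19 and MCM2 at 0.79 ± 0.18. Both of these calls were lost on thinning to 500 UMIs (adjusted p = 0.0948 and 0.904).

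Immediate early genes were lower in ENTPD1-positive cells in 12 of 18 cases, 14 adjusted over the list alone (adjusted p = 1.10e-14; adjusted p = 0.0501 with an estimated correlation), with EGR1 at −1.01 ± 0.19, FOS at −0.77 ± 0.10 and NR4A1 at −0.70 ± 0.11. Heat shock genes, higher in tumour than in blood, were lower in these cells in 8 of 15 cases, 9 adjusted over the list alone (adjusted p = 5.86e-07; adjusted p = 0.127 with an estimated correlation), with HSPA6 at −0.87 ± 0.10 and DNAJB1 at −0.64 ± 0.08. That list's call was lost without the replicate block (adjusted p = 0.195). Of 6 MAIT genes 3 were lower, 4 adjusted over the list alone (adjusted p = 9.72e-04; adjusted p = 0.111 with an estimated correlation), with RORA at −0.70 ± 0.12. The circulating effector list split, 7 of 16 members being higher and 4 lower, 5 lower adjusted over the list alone (adjusted p = 0.154, median 0.12 and mean −0.13). The adhesion receptor gene ADGRG1 (0.86 ± 0.11) was higher, and the homing genes KLF3 (−2.37 ± 0.18) and S1PR5 (−1.95 ± 0.39) were lower. S1PR5 was at 0 to 10.3 CPM in the ENTPD1-positive arms, so that the size of its fall rests on few molecules too. Tissue-residency genes split as well, 5 of 11 being higher and 4 lower (adjusted p = 0.0615), with CXCR6 at 0.84 ± 0.08 and RGS1 at 0.55 ± 0.08. Of 14 cytokine genes 4 were higher and 3 lower, 6 higher adjusted over the list alone (adjusted p = 0.104), with CCL3 at 0.79 ± 0.10 and TNF at −1.10 ± 0.15. Of 14 glycolysis and hypoxia genes 4 were higher and 2 lower (adjusted p = 0.0749), with PKM at 0.47 ± 0.08 and the glucose transporter gene SLC2A3 at −0.53 ± 0.08. Of 16 interferon-response genes 1 was higher and 1 lower, 2 lower adjusted over the list alone (adjusted p = 0.349, median 0.0399 and mean −0.0033). No oxidative phosphorylation gene of 16 passed (adjusted p = 0.754, median 0.01 and mean −0.02). None of 3 chemokine receptor genes did, 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.550). Outside the lists, PLAC8 (−2.11 ± 0.11), C1orf162 (−2.41 ± 0.19), TIMP1 (−1.50 ± 0.15), SORL1 (−1.43 ± 0.17) and the growth regulator MYC (−1.52 ± 0.18) fell and MS4A6A (1.01 ± 0.14) and GOLIM4 (0.94 ± 0.13) rose. Of other cell types, S100B was lower (−1.53 ± 0.25), and B and plasma genes were higher in 2 and lower in 1 of 5 cases (adjusted p = 0.213). AIF1, 1 of 2 myeloid genes (adjusted p = 0.351), and KRT10 were lower (−0.45 ± 0.14 and −0.21 ± 0.07). These were calls that leaving out patient 4, 7 or 8 and patient 1, 2, 3, 5, 6 or 7 ended (adjusted p = 0.0624 to 0.309 and 0.0525 to 0.109). DESeq2 did not call AIF1 or KRT10 either (adjusted p = 0.333 and 0.0598), nor did the fit without the replicate block (0.916 and 0.970). KRT10 was also lost on thinning to 500 UMIs (0.270) and among cells with CD8 and no CD4 transcript (0.0522). Of 4 gamma delta genes none passed, 2 being higher adjusted over the list alone (adjusted p = 0.383). IKZF2 of the CD4 and regulatory list did not pass (0.39 ± 0.19, adjusted p = 0.215). It was higher only when adjusted over the list alone (unadjusted p = 0.0416, edgeR). PECAM1 was at −0.06 ± 0.12, and no erythroid or platelet gene was measured.

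**Figure D3:**
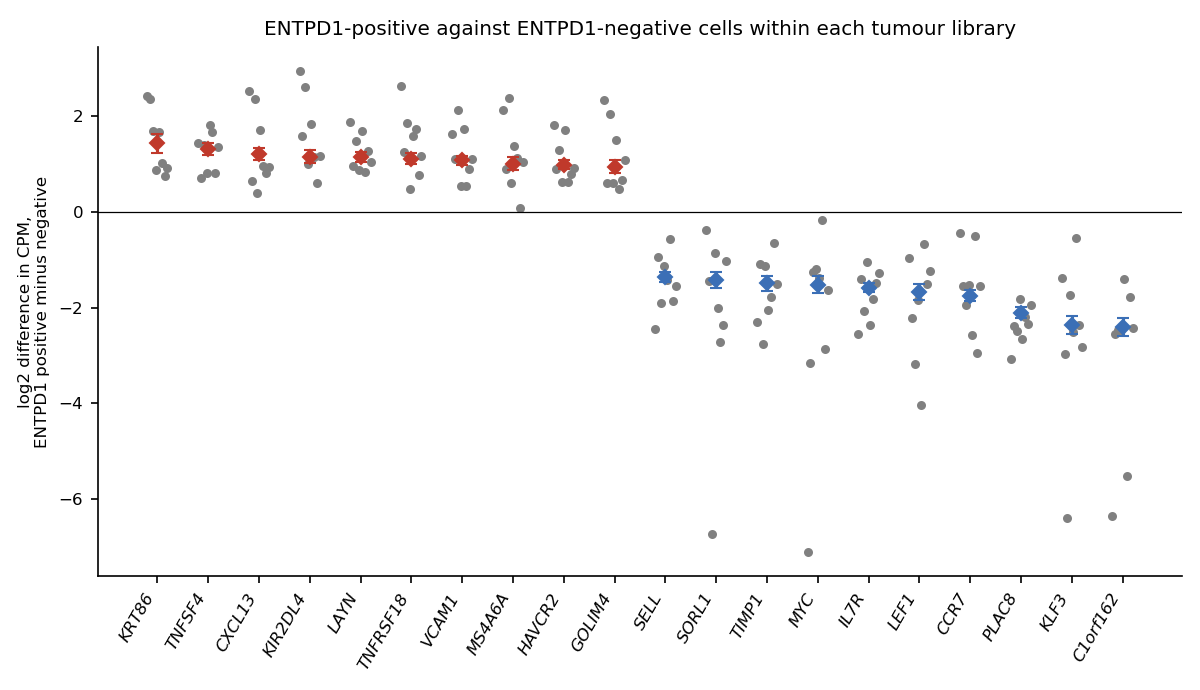
Log2 difference in CPM between ENTPD1-positive and ENTPD1-negative cells of the same tumour library for the 10 genes with the largest rise and the 10 with the largest fall; grey points are the 8 libraries and diamonds the fitted log2 fold change with 1 SE. KRT86 stands highest at 1.43 and C1orf162 lowest at −2.41.

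Because each patient gave both tissues, the level of each list in blood was set against that in tumour across the 8 patients. No list's blood level followed its tumour level beyond chance. The closest relation was that of naive and central memory genes, whose mean log2 CPM went in opposite directions (Pearson r = −0.69, p = 0.0657; Spearman rho = −0.64, p = 0.0962; exact permutation of the 40320 pairings). After Benjamini-Hochberg adjustment over the 15 lists its p was 0.648 for r and 0.649 for rho, and r was −0.45 without the 2 patients farthest from the median in blood. Exhaustion genes had r = −0.21 and rho = −0.26 (exact permutation p = 0.593 and 0.536), circulating effector genes r = 0.05 and rho = 0.29 (exact permutation p = 0.907 and 0.501). Immediate early genes had r = 0.61 and rho = 0.36 (exact permutation p = 0.104 and 0.389), and r was −0.02 without the 2 farthest patients, so that this value rested on them. None of the 15 lists had an unadjusted p under 0.05, the lowest adjusted p was 0.648, and the labels name no sequencing batch within which to recompute the relations.

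**Figure D4:**
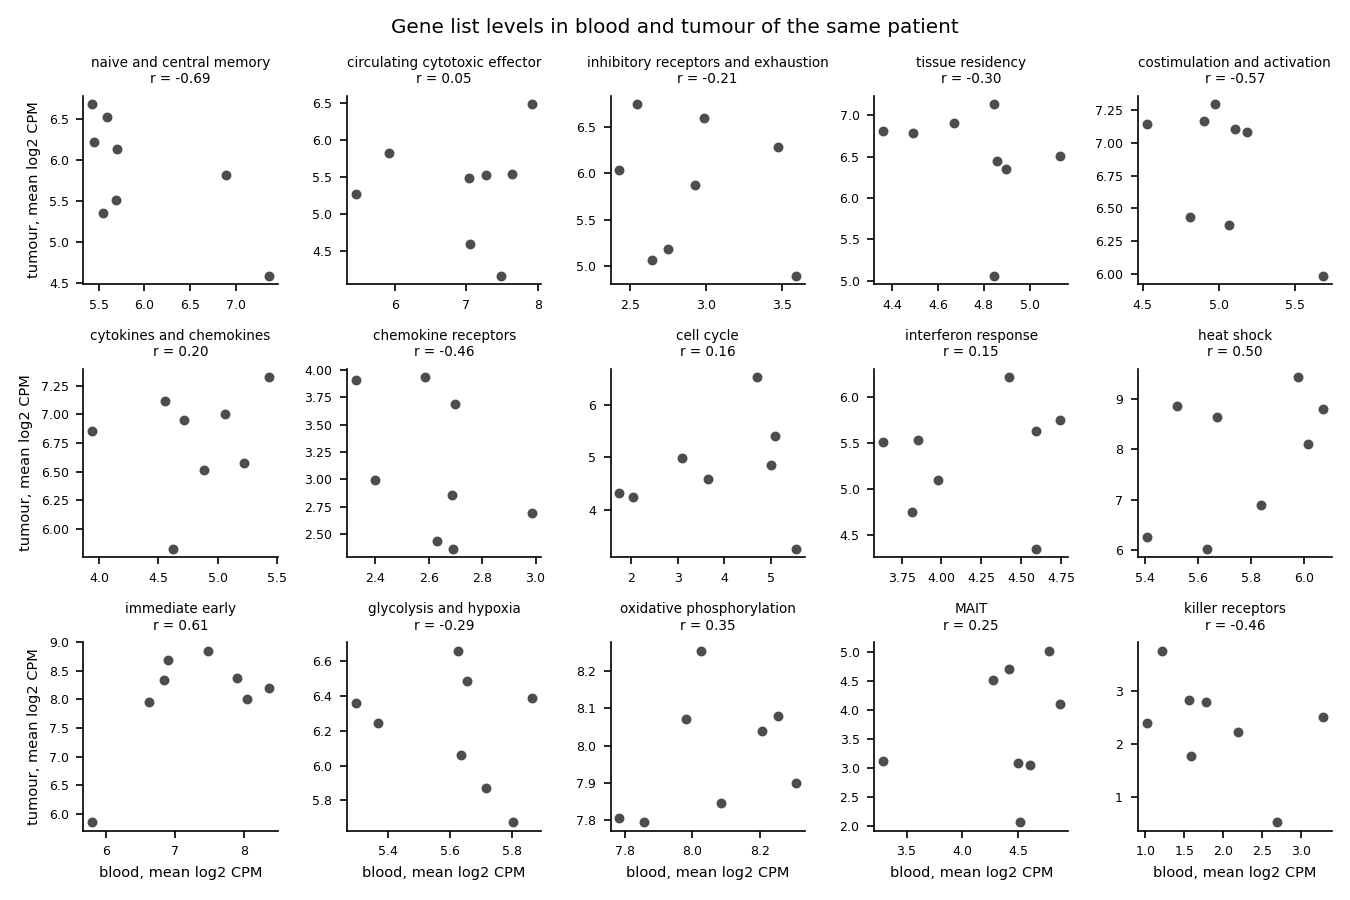
Mean log2 CPM of the 15 functional lists in the blood (horizontal axis) and tumour (vertical axis) libraries of the same patient, 1 point per patient, with Pearson's r over each panel. The naive and central memory panel has the most negative r, −0.69, and the immediate early panel the most positive, 0.61.

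Clustering the 165097 filtered cells described the states behind these sums. Of 18 clusters, 1 of 1230 cells, 315 of them from tumour, was not of the T lineage. It held S100A8, LYZ and FCN1, and was mixed, with the melanocyte genes DCT in 7.64% and APOD in 10.3% of its cells. A circulating effector-like cluster of 15830 cells was led by FGFBP2, KLRF1 and PRSS23 and held 206 tumour cells, and a naive or central memory-like cluster of 15405 cells was led by MAL, LEF1 and CCR7. A cluster of 9815 cells, 9790 of them from tumour, held CCR7 and LEF1 together with HSPA6. There were 2 proliferating-like clusters, 1 of 4629 cells, 266 of them from tumour, led by RRM2, PCLAF and TYMS, and 1 of 2957 cells, all from tumour, led by UBE2C and TOP2A. The clusters with most exhaustion markers raised over other cells came mostly from 1 library each. They held 7362 cells with 9 of 9 markers (93.4% from tumour library 7), 12360 with 8 (91.9% from tumour library 4) and 6861 with 6 (93.2% from tumour library 8). In 7 clusters, 6 of tumour and 1 of blood, at least 90% of the cells came from 1 library. Of the cells of tumour library 2, blood library 8 and tumour library 4, 98.4%, 85.6% and 82.4% lay in such clusters of their own. Cluster sizes were therefore not compared between tissues.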

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

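No test in this part was chosen after the result was seen. A library is named here where the highest or lowest of the 8 libraries of a group lay so far from its nearest neighbour that the gap made up more of the group's range than the 95% critical value of Dixon's test allows, and the number given as the gap is that share of the range. Of 520 groups of values 46 (8.85%) met this rule, while chance alone marks about 1 in 20 if values are normally distributed, so that part of these results is what chance gives. The groups overlap, since many genes enter in the T-cell gate, the CCL5 gate within it and the ENTPD1 arms. The 46 are therefore not independent results, and 1 library can recur through the same gene.

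Tumour library 2 stood apart most often, with low immediate early transcripts and a low mean over the tissue-residency list. Its mean log2 CPM over the immediate early list was 5.86 against a mean of 8.35 of the other 7 tumour libraries (gap 0.702), and over the residency list 5.06 against a mean of 6.70 (gap 0.621). Residency genes did not fall together there, as CXCR6 was at a log2 CPM of 7.99, the highest of the 8 tumour libraries. In the T-cell gate NR4A1 was at a log2 CPM of 0.66 against a mean of 6.13 (gap 0.652), JUNB at 7.93 against a mean of 11.09 (gap 0.648), JUND at 6.16 against a mean of 8.22 (gap 0.711) and TRGC2, a T-cell receptor gamma constant gene, at 5.03 against a mean of 8.37 (gap 0.729). In the CCL5 gate the gaps of this library were 0.663 for NR4A1, 0.662 for JUNB, 0.737 for JUND and 0.861 for TRGC2. Among its ENTPD1-negative cells they were 0.655 for NR4A1, 0.614 for ZFP36, 0.796 for TRGC2, 0.609 for CCL4, 0.536 for RGS1, 0.623 for CD244 and 0.596 for SLC2A3. Among its ENTPD1-positive cells they were 0.708 for NR4A1, which had no count there, 0.534 for ZFP36, 0.541 for CCL4, 0.589 for RGS1 and 0.587 for TNFRSF9. In each of these cases the library was the lowest of the 8.

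Blood library 6 was rich in naive-like cells. CCR7 was found in 17.3% of its thinned cells against a mean of 2.49% in the other 7 blood libraries (gap 0.618), the CCL5 gate took in 32.8% of its cells against 89.3% (gap 0.589), and its MAIT list was at a mean log2 CPM of 3.29 against a mean of 4.57 (gap 0.624). In blood library 8, IFNG was found in 20.6% of cells against 3.93% (gap 0.736), and ATF3 was at 5.64 against a mean of 1.51 log2 CPM in the T-cell gate (gap 0.599) and 5.88 against a mean of 1.84 in the CCL5 gate (gap 0.559). In blood library 1 the T-cell gate kept 70.3% of cells against 98.1% (gap 0.706), CXCR3 was at 4.27 against a mean of 5.50 log2 CPM (gap 0.542), and HMGB2 in the CCL5 gate at 8.07 against a mean of 8.76 (gap 0.575). In the CCL5 gate of blood library 2, KIR2DL4 was at 1.08 against a mean of −1.22 log2 CPM (gap 0.554) and LAYN at 1.23 against a mean of −1.61 (gap 0.561). In the other blood libraries KIR2DL4 lay between −1.95 and −0.60 and LAYN between −1.95 and −0.55, where −1.95 is the log2 CPM of a gene without a count. Even in blood library 2 they were at only 1.86 and 2.09 CPM. These gaps therefore rest on few molecules. HIF1A was at 5.42 against a mean of 4.49 log2 CPM in blood library 5 (gap 0.537).

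Tumour library 1 kept the most FGFBP2 and CX3CR1. FGFBP2 was in 10.2% of its cells against a mean of 1.08% in the other 7 tumour libraries (gap 0.855) and CX3CR1 in 0.279% against 0.0278% (gap 0.766). In its CCL5 gate FGFBP2 was at 7.71 against a mean of 3.58 log2 CPM (gap 0.602) and CX3CR1 at 1.69 against a mean of −0.86 (gap 0.578). Among its 82 ENTPD1-positive cells CD28 was at 3.43 against a mean of 5.45 (gap 0.710), and MAL had no count (gap 0.631). That arm held 81190 UMIs of tested genes. CD28 at 10.3 CPM and MAL therefore rest on few molecules, and both gaps may be counting error. Among the 190 ENTPD1-positive cells of tumour library 3, BNIP3 had no count (gap 0.639), GNLY was at 5.78 against a mean of 9.49 (gap 0.555), RUNX3 at 5.78 against a mean of 7.74 (gap 0.564) and TNFSF14 at 4.66 against a mean of 3.08 (gap 0.673). With 188375 UMIs of tested genes in that arm, the values of BNIP3 and TNFSF14 may be counting error as well. In tumour library 6, MKI67 was in 5.13% of cells against 1.18% (gap 0.773), and MAL was at 1.81 against a mean of 5.01 log2 CPM in ENTPD1-negative cells (gap 0.572).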

How the results depend on the processing

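Of the alternatives below, those without the cells of highest doublet score, without the barcodes that blood library 4 and tumour library 5 share, and without patients 1 and 2 were chosen after the data were seen. No result changed direction while called under any alternative. In the T-cell gate the higher genes numbered 1064 to 1546 and the lower 649 to 1160 with a patient left out in turn. By at least 1 log2, 1285 were higher and 586 lower with DESeq2, and 1248 were higher with no filter on low counts, which tests more genes. In the CCL5 gate the lower genes numbered 780 to 1292 with a patient left out. By at least 1 log2, 1087 were higher and 536 lower with DESeq2, and 1179 and 532 with no filter on low counts. Between ENTPD1 arms no gene was called without the replicate block (0 higher and 0 lower, and 0 and 0 by at least 1 log2, in edgeR, with 655 genes at an unadjusted p under 0.05), since the spread between patients then enters the error. DESeq2 called 260 higher, 37 of them by at least 1 log2, and thinning to 500 UMIs left 185 higher and 294 lower. With no filter on low counts 893 were lower, and 31 higher and 210 lower by at least 1 log2. With CD8 detected and no CD4, 13 were higher by at least 1 log2, and with a patient left out 282 to 445 were higher, 10 to 42 of them by at least 1 log2. With an estimated correlation, the lists called higher went from 9 to 4 and lower from 1 to 0 in the T-cell gate, from 10 to 5 and from 3 to 0 in the CCL5 gate, and lower from 4 to 1 between ENTPD1 arms. Without patients 1 and 2 the lists called lower in the T-cell gate went from 1 to 2. Except where given, the cause was not tested. The other counts lay within 1.5 times the reported ones, the 15 higher and 2 lower shares staying at 14 to 16 and 2 with a patient left out, and no list relation passing under any setting (0). Of single results, 187 of 210 for lists, 344 of 350 for shares, 1490 of 1515, 1477 of 1518 and 1031 of 1148 for named genes of the 3 comparisons, and 30 of 30 for relations kept their side of the threshold. Of those that did not, 20, 4, 20, 32, 104 and 0 lost the call and 3, 2, 5, 9, 13 and 0 gained it, 54 of the 104 without the replicate block. Among these single results, apart from CD79B, KLF2, RUNX3, the MKI67 share, the comparison of ENTPD1 arms and its heat shock list (adjusted p = 0.195), the block changed no call at the preset correlation between genes. Over all genes, the fit with the block called more in both comparisons of tumour with blood, as given with the processing. The planned run without cells called doublets by scrublet's automatic threshold was not run, as that threshold marked almost no or almost all cells of most libraries.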

Other observations

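The genes in this and the next paragraph, and every test in this part except that of IGKC in cells with MZB1, were chosen after the result was seen. Granule genes, the killing machinery of CD8 T cells, did not move together between tissues. GZMB, granzyme B, was at 757 ± 414 CPM in tumour and 389.6 ± 229 CPM in blood (log2 fold change 0.96 ± 0.45, adjusted p = 0.140) and PRF1, perforin, at 0.47 ± 0.40 (adjusted p = 0.441), neither past the threshold. GZMH fell from 1048 ± 451 to 441 ± 181 CPM (−1.25 ± 0.35, adjusted p = 0.0161, lower in 6 of 8 patients), GZMM by a log2 change of −1.07 ± 0.25 (adjusted p = 0.00561, lower in 8 of 8) and GNLY, granulysin, by −1.24 ± 0.38 (adjusted p = 0.0280, lower in 7 of 8). GZMA (−0.11 ± 0.29, adjusted p = 0.825) and GZMK (0.31 ± 0.30, adjusted p = 0.497) did not pass. Inside tumours, ENTPD1-positive cells held more GZMB (0.72 ± 0.08, adjusted p = 1.77e-09, higher in 8 of 8 libraries), PRF1 (0.61 ± 0.08, 8 of 8) and GZMH (0.46 ± 0.07, 7 of 8) and less GZMM (−0.35 ± 0.08, lower in 8 of 8) than ENTPD1-negative cells. GNLY (0.19 ± 0.14, adjusted p = 0.512), GZMA (0.21 ± 0.08, adjusted p = 0.0761) and GZMK (−0.17 ± 0.09, adjusted p = 0.266) did not pass there.

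Transcription factors of effector and exhausted cells differed likewise. TBX21, or T-bet, fell in tumour (−1.07 ± 0.27, adjusted p = 0.00970, lower in 7 of 8 patients), while its relative EOMES did not pass (0.32 ± 0.36, adjusted p = 0.574). TOX2 rose from 1.67 ± 1.11 to 22.9 ± 20.3 CPM (3.79 ± 0.59, adjusted p = 2.51e-04, 8 of 8 patients) and ID3 from 5.34 ± 5.97 to 84.4 ± 44.1 CPM (3.95 ± 0.59, adjusted p = 1.81e-04, 8 of 8). Between ENTPD1 arms TOX2 was higher in positive cells (0.55 ± 0.13, adjusted p = 0.00321), and TBX21 (0.05 ± 0.12, adjusted p = 0.904), EOMES (0.13 ± 0.09, adjusted p = 0.446) and ID3 (0.12 ± 0.09, adjusted p = 0.509) did not pass. The regulatory cytokine gene IL10 rose in tumour from 1.62 ± 0.839 to 9.07 ± 8.49 CPM (2.49 ± 0.55, adjusted p = 0.00416, 7 of 8 patients).

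Heat shock genes were higher in tumour. ENTPD1-positive cells held less HSPA6 than ENTPD1-negative cells of the same library (−0.87 ± 0.10, lower in 8 of 8 libraries). This cannot decide on free RNA spread evenly over the tumour droplets. After thinning, such RNA takes a smaller share of cells with more RNA, and depth before thinning was not compared between the arms. Handling of the tumour samples, such as the digestion that frees cells, cannot be told apart from the tissue itself, since any such step goes with tissue in every pair of libraries. HSPA1A was in 58.4% of the 77 barcodes of other cell types in tumour and in 2.61% of the 612 in blood. Both are pooled over libraries. Handling of the whole sample or free RNA would give such shares, but the tissue could give them too. That the tumour raised these genes in its T cells stays open as untested.

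B and plasma cell genes were higher in tumour. ENTPD1-positive cells held more MZB1 than ENTPD1-negative cells of the same library (0.52 ± 0.14, adjusted p = 0.00922, edgeR). For MZB1 this argues against evenly spread free plasma cell RNA, unless ENTPD1-positive cells held less RNA before thinning, which was not compared. Doublets of T and plasma cells cannot be told apart from expression of MZB1 by T cells, which stays open as untested, because the gate removed barcodes with 3 or more UMIs of other cell types, MZB1 among them. In the cells it left, 8.47% of 4405 tumour cells with MZB1, pooled over libraries, also held IGKC (373 cells), a share the gate keeps low whatever the cause. Most of these came from tumour library 4, with 216 of 1546 cells with MZB1 against 1288 of 11925 without, and tumour library 8, with 109 of 785 against 1098 of 11607, while tumour library 5 had 0 of 330. For IGKC, free RNA remains a candidate source, with a difference between the arms of −0.32 ± 0.18 within 2 standard errors of 0.

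Blood library 4 and tumour library 5, from different patients, shared 778 barcodes where 331 were expected, 2.35 times as many, while no other of the 120 pairs of libraries exceeded 1.28 times, so that chance reuse of barcodes is argued against. For 75.6% of the shared barcodes (588) the cell in blood library 4 with the same barcode was the most alike of 51 compared, where chance gives 1.96%, which suggests that molecules of blood library 4 were assigned to tumour library 5. The shared barcodes made up 6.68% of those of tumour library 5, with a median of 997.5 UMIs there and 5252 in blood library 4. Without them, 1530 genes were higher and 1063 lower in the T-cell gate.

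Regrouping the libraries tested chance as the source of the counts of changed genes, and it is argued against in each comparison. In the T-cell gate the real grouping called 2575 genes, and of 100 splits of the 16 libraries, the real one included, only that 1 gave as many, the highest other calling 605. Of 100 splits that part every patient's libraries, again only the real 1 did, the highest other calling 1159. In the CCL5 gate the real grouping called 2722 genes, in 1 of 100 splits each, with 664 as the highest other over all splits and 982 over those that part every pair. Between ENTPD1 arms 994 genes were called, in 1 of 100 exchanges of the arms within libraries, and the highest other called 614.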
